A study of Homo sapiens with 12 samples.

How the data were processed

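Total RNA and m6A-immunoprecipitated RNA were measured in C4-2 prostate cancer cells with an empty vector (NC) or ALKBH5 overexpression (oeALKBH5), with 3 input and 3 IP libraries per group and 12 samples in all. Per the labels' protocols, ribosomal RNA was removed from total RNA, m6A immunoprecipitation was done with a commercial kit, and directional libraries were sequenced as 150 base paired ends on an Illumina NovaSeq instrument. The submitters' processing notes name cutadapt 1.9.3, HISAT2 2.0.4, Cuffdiff and Cufflinks and the genome build hg19, without the role or order of each.

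Gene values of the input libraries are FPKM (fragments scaled to transcript length and to mapped fragments) as deposited by the authors; the table names no unit, and FPKM follows from the tools the submitters' processing notes name and from the values. The peak lists hold 1 list per IP library, and the score of each peak is the authors' score as deposited, which from the peak names and its minimum of 50 is the score the peak caller MACS writes. The version and options of the caller and the control it used are not stated. All 6 lists held 3328 identical intervals, and peaks were as short as 1 base. The list of NC replicate 1 held 11902 peaks with numbers up to 152176. The lists thus seem to have been filtered or cut after calling, by steps not stated. Counts, widths, covered lengths and overlaps therefore describe the lists as deposited. Counts of reads were not used here, so the absolute depth of each library is unknown, and no interval that needs counts was computed. The depth relative to NC replicate 1 was estimated from the commonest ratio of values among genes under 1 FPKM in every library. Samples were grouped by the genotype in the labels.

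Of 20308 genes in the table, 19434 had a symbol in the gene name tables used. Genes with a mean of at least 0.5 FPKM over the 6 input libraries were tested, 12757 in all. Values were transformed to log2(FPKM + 1) and fitted with limma 3.58.1 in R 4.3.3, with an intensity trend in the moderated variance, and p-values were adjusted by Benjamini-Hochberg over all tested genes with a threshold of 0.05. A fold change is oeALKBH5 minus NC on that log2 scale, which understates the change of low genes. ALKBH5, CLSPN and IGF2BP2 also had an exact permutation test. A value above 0 and under 1e-06, found in 431 genes, was taken as a failed split of reads between overlapping genes or copies.

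Written before the values were seen, 25 gene lists held pathways, cell identities and markers of other cell types; 14 of their genes were not matched in the table. Lists with at least 5 tested members, 24 of them, were tested with camera of limma at a preset correlation between genes of 0.01, adjusted by Benjamini-Hochberg over lists. Members were also adjusted over the list alone. The lists were the type I interferon response, NF-kB and TNF response, immediate early and heat shock, unfolded protein and ATF4 response, hypoxia and glycolysis, cholesterol synthesis, fatty acid synthesis, oxidative phosphorylation, mitochondrially encoded genes, DNA replication, histones, replication checkpoint, mitosis, MYC targets, ribosomal proteins, p53 targets, androgen receptor targets, luminal, basal and neuroendocrine identity, epithelial-mesenchymal transition, docetaxel response, m6A machinery, and fibroblast and immune cell markers.

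Peaks of the 6 IP libraries that overlap by at least 1 base on the same strand were joined into regions. A region was called lost when all 3 NC and no oeALKBH5 lists held a peak in it, and gained in the reverse case. Numbers of peaks, widths, covered length and scores were compared by exact permutation of the 6 libraries, for which the smallest p is 0.1 at 3 against 3. The overlap of libraries was measured by the Jaccard index of covered bases and by the share of peaks that overlap, within against between groups, exact over the 10 splits. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used. Positions of peaks in transcripts, the expression of genes with lost or gained regions and gene lists among those genes were planned but not analysed here, since they need an annotation or sequence of hg19.

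Genes were named by a rule written before the values were seen: ALKBH5, CLSPN and IGF2BP2; the 10 largest rises and 10 largest falls among called genes with a mean of at least 1 FPKM and groups that did not overlap; up to 4 members per list with the smallest p; members of the m6A machinery; and the 10 lost and 10 gained regions with the highest mean within-list rank of score, of which the condition that their gene be in the table was dropped. Exceptions are marked in the text as chosen after their values were seen, and some genes that the rule names are not reported here.

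The steps were tested on simulated data with known answers. For the oeALKBH5 against NC comparison of 12757 genes, limma recovered 53% of 100 genes changed by 1 on the log2 scale and 87% of 100 changed by 2, with 5 false calls. The changed genes were drawn from those with an NC mean above 2 on the log2(FPKM + 1) scale, so recovery of lower genes was not tested. Camera called a DNA replication list lowered by 0.5 and 0 other lists. The simulated genes varied independently, whereas genes of the real mitosis list had an estimated correlation of 0.53. The simulation therefore does not show how often camera falsely calls lists of correlated genes. In simulated peaks of 6 libraries, all 120 lost and 240 gained regions were found.

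The alternatives tried were a pseudocount of 0.1, no filter and a minimum mean of 2 FPKM, upper quartile scaling, quantile normalization, limma without trend, a replicate block, camera with an estimated correlation, the rotation test fry, leaving out each library in turn, peaks of the upper part of each list by score, merging overlapping peaks of a list, overlap of at least 50% of the shorter peak, equal numbers of peaks, and regions in at least 2 of 3 libraries. Chosen after the data were seen, 4 more were joining peaks without regard to strand, peaks of at least 50 bases, and leaving out genes with a failed estimate, for genes and for lists.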

Results

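m6A-modified RNA and total RNA were measured in C4-2 cells, an established line of castration-resistant prostate cancer, that carried either an empty vector (NC) or an ALKBH5 overexpression construct (oeALKBH5). ALKBH5 is a demethylase that removes N6-methyladenosine (m6A) from RNA. Each group had 3 replicates, and each replicate gave 1 library of RNA pulled down with an m6A antibody (IP) and 1 input library made without the pull-down, 12 libraries in all. The labels do not say whether the replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Expression values were available as FPKM for 20308 genes. The library sums ranged from 511333 to 524905 FPKM, and absolute sequencing depth is unknown. From the commonest ratio of values among low genes, which hold few reads, the inputs had depths of 1.00, 1.13 and 1.00 in NC replicates 1, 2 and 3, and 1.07, 0.783 and 0.83 in oeALKBH5 replicates 1, 2 and 3, all relative to NC replicate 1. The ratios rested on few of the genes compared, 80 of 470 in oeALKBH5 replicate 2 and 90 of 515 in oeALKBH5 replicate 3. If these depths hold, low genes were measured least precisely in oeALKBH5 replicates 2 and 3.

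The first comparison asked how far ALKBH5 itself was raised and whether CLSPN and IGF2BP2, named with it in the study's question, differed between the groups. ALKBH5 mRNA went from 61.4 ± 3.39 to 75.7 ± 4.05 FPKM (mean ± SD, n = 3 per group), with all 3 oeALKBH5 libraries above all 3 NC libraries. This difference of 0.30 on the log2(FPKM + 1) scale (SE 0.10) did not pass the limma test over all genes (adjusted p = 0.114). Whether the gene's value holds all reads of the introduced sequence is not known here, so it is an uncertain measure of overexpression. CLSPN, which encodes claspin, an adaptor that activates the checkpoint kinase CHK1 at stalled replication forks, fell from 19.7 ± 1.83 to 7.03 ± 1.08 FPKM, a log2 fold change of -1.37 (SE 0.18, limma adjusted p = 0.0046). IGF2BP2, an m6A-binding protein that stabilises its target mRNAs, rose from 2.49 ± 0.729 to 8.26 ± 2.97 FPKM, a log2 fold change of 1.38 (SE 0.31, limma adjusted p = 0.0383). An exact permutation test on each of the 3 genes gave p = 0.1, the smallest that 3 libraries against 3 can give. The IGF2BP2 call was lost in 5 of the 6 fits that left out 1 library: its limma adjusted p was 0.11 without NC replicate 1, 0.0675 without NC replicate 2, 0.116 without NC replicate 3, 0.104 without oeALKBH5 replicate 1 and 0.101 without oeALKBH5 replicate 2.

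**Figure D1:**
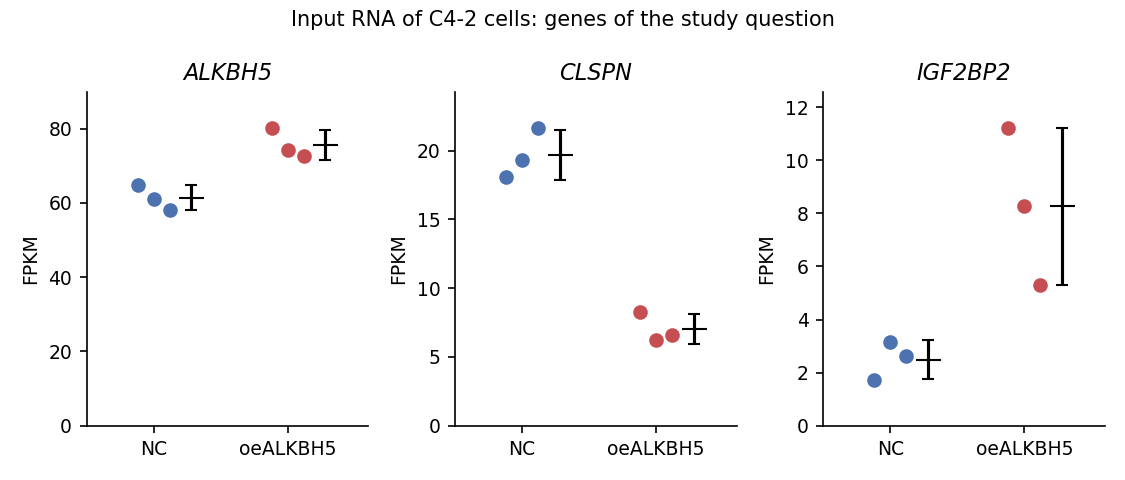
FPKM of ALKBH5, CLSPN and IGF2BP2 in the 3 NC (blue) and 3 oeALKBH5 (red) input libraries; points are libraries, and the black marks give the mean ± SD. The means were 61.4 to 75.7 for ALKBH5, 19.7 to 7.03 for CLSPN and 2.49 to 8.26 for IGF2BP2, and in each gene the groups did not overlap.

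The second comparison asked which genes differed in input RNA. The largest rises included antiviral genes. IFIT1, which binds foreign RNA 5′ ends, rose from 1.76 ± 0.311 to 143 ± 35.4 FPKM (log2 fold change 5.69, SE 0.20, limma adjusted p = 3.94e-06). Its relatives IFIT3 and IFIT2 rose from 1.16 ± 0.691 to 50.6 ± 6.44 FPKM and from 2.91 ± 1.31 to 92.9 ± 20.2 FPKM, and OASL rose from 1.84 ± 0.779 to 84.4 ± 12.7 FPKM. RSAD2, which encodes the antiviral enzyme viperin, was listed at 0 in 2 NC libraries and at 0.0893 FPKM in the other, and at 31.5, 38 and 23 FPKM in the oeALKBH5 libraries. The chemokine CXCL10 rose from 1.84 ± 1.46 to 52.8 ± 20.7 FPKM, the complement factor CFB from 0.457 ± 0.418 to 19.4 ± 2.92 FPKM and PLAAT4 from 1.59 ± 0.0555 to 34.9 ± 6.89 FPKM. RAET1L, a ligand of the natural killer cell receptor NKG2D, was listed at 0 in all 3 NC libraries and at 14.4, 15.8 and 12.3 FPKM in the oeALKBH5 libraries. The tenth of the largest rises, the gene ENSG00000242631 with no symbol in the tables used, rose from 1.65 ± 2.86 to 22.7 ± 7.36 FPKM. Its NC values were 4.95, 1.75e-08 and 1.13e-10 FPKM, of which the last 2 are failed estimates, so the size of this rise is uncertain.

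Among the largest falls, RAMP1, a coreceptor for the neuropeptide CGRP, went from 17 ± 0.908 to 4.77 ± 1.16 FPKM (log2 fold change -1.66, SE 0.21, limma adjusted p = 0.00379). NAALAD2 went from 5.39 ± 0.526 to 0.535 ± 0.373 FPKM, the organic cation transporter SLC22A3 from 8.97 ± 3.59 to 1.07 ± 0.971 FPKM, and PDIA2 from 5.13 ± 2.45 to 0.901 ± 0.767 FPKM. OVGP1 went from 7.14 ± 1.63 to 1.81 ± 1.09 FPKM, C4orf48 from 3.65 ± 0.642 to 0.409 ± 0.709 FPKM and IRF9 from 6.54 ± 1.92 to 1.54 ± 0.636 FPKM. NKAIN2 was listed at 1.96, 2.75 and 3.23 FPKM in the NC libraries and at 0 in all 3 oeALKBH5 libraries. GPR89B fell from 10.7 ± 3.46 to 0.577 ± 0.804 FPKM, but its near-identical copy GPR89A stood at 12 ± 3.75 FPKM in NC and 18.7 ± 7.89 FPKM in oeALKBH5 libraries, so reads shared by the copies leave this fall uncertain. The fall of the readthrough gene NEDD8-MDP1, which overlaps NEDD8 and MDP1, is uncertain for the same reason. So is that of IRF9, whose neighbour RNF31 stood at 16.6 ± 8.39 FPKM in NC and 26.6 ± 2.06 FPKM in oeALKBH5 libraries and was lowest, at 6.89 FPKM, in NC replicate 2, where IRF9 was highest, at 8.75 FPKM. The limma calls of 8 of these 20 largest rises and falls were lost in at least 1 fit that left out 1 library: ENSG00000242631, SLC22A3, NKAIN2, NEDD8-MDP1, C4orf48, PDIA2, OVGP1 and IRF9, with the highest adjusted p, 0.141, for PDIA2 without NC replicate 1. IRF9 lost its call without NC replicate 1, NC replicate 2, NC replicate 3, oeALKBH5 replicate 1 and oeALKBH5 replicate 3 (adjusted p up to 0.0849, without NC replicate 2).

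In all, limma called 695 of 12757 tested genes, 385 higher and 310 lower in oeALKBH5. Of these, 188 rose and 65 fell by at least 1 on the log2 scale. The groups did not overlap in 3584 genes, 28.1% of those tested, where chance gives 10%. Leaving out 1 library lowered the number of calls in each case, from 436 without oeALKBH5 replicate 1, 387 without NC replicate 1, 367 without oeALKBH5 replicate 2, 325 without NC replicate 2 and 282 without oeALKBH5 replicate 3 down to 232 without NC replicate 3.

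Of 29 tested members of the type I interferon list, 15 rose, 1 fell and 13 did not pass the test (17 rose and 2 fell when adjusted over the list alone), with a mean log2 fold change of 1.67. Beside the genes above, the cytosolic RNA sensor RIGI rose from 3.26 ± 0.752 to 41.9 ± 3.38 FPKM and the ubiquitin-like modifier ISG15 from 15.3 ± 1.95 to 141 ± 36 FPKM, both chosen after their values were seen. The member that fell, with the uncertainty given above, was IRF9, a subunit of the transcription factor complex that acts downstream of the interferon receptor. Camera called the list higher (adjusted p = 2.84e-13; adjusted p = 0.12 with an estimated correlation). In the list of NF-kB and TNF response genes, 2 of 14 members rose, BIRC3 from 2.8 ± 0.107 to 11.1 ± 2.05 FPKM and TNFAIP3 from 2.26 ± 0.334 to 5.91 ± 1.35 FPKM, and 12 did not pass the test (also 2 rising when adjusted over the list alone). TNFAIP3 lost its call in each of the 6 fits that left out 1 library, with adjusted p up to 0.145 without oeALKBH5 replicate 3. The list was called higher (camera adjusted p = 0.0323; adjusted p = 0.168 with an estimated correlation), but not without NC replicate 1 (adjusted p = 0.0932) or without oeALKBH5 replicate 2 (adjusted p = 0.0766). Of 17 immediate early and heat shock genes, 5 rose and 3 fell (8 and 5 when adjusted over the list alone), among them the stress-induced transcription factor ATF3, from 17.3 ± 1.53 to 59.4 ± 6.98 FPKM, and the constitutive chaperone HSPA8, from 1039.5 ± 63.3 to 760.3 ± 63.7 FPKM. The list as a whole was not called (camera adjusted p = 0.191). HSPA8 lost its call without NC replicate 3 (adjusted p = 0.0537). Of the 13 immune cell markers in the table, 3 were tested, CD3D, CD3E and LYZ, and none was called by limma over all genes; 1, CD3D, passed when adjusted over the list alone. The highest mean among the 13 was 2.32 FPKM in oeALKBH5 libraries, for LYZ, which limma called over all genes without oeALKBH5 replicate 2 (adjusted p = 0.0339).

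**Figure D2:**
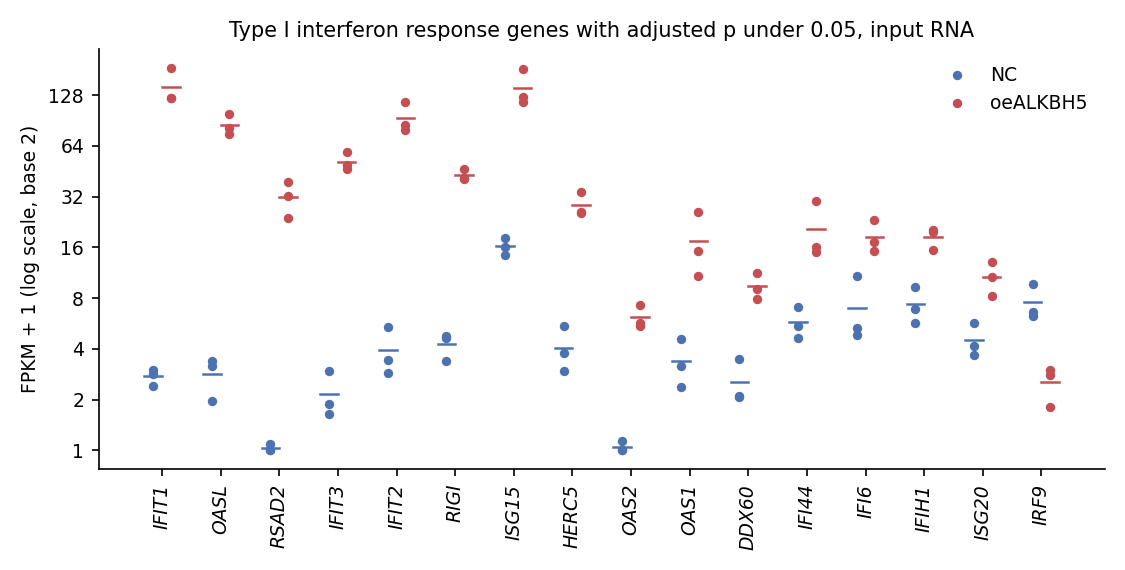
FPKM + 1 (log axis, base 2) of the 16 type I interferon response genes that limma called, in the 3 NC (blue) and 3 oeALKBH5 (red) input libraries, ordered by log2 fold change; points are libraries and short lines are group means. IFIT1 went from 1.76 to 143 FPKM, and IRF9 from 6.54 to 1.54 FPKM.

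Genes of hypoxia and glycolysis rose together. Of 32 tested members, 17 rose, none fell and 15 did not pass the test; 27 rose and 1, TPI1, fell when adjusted over the list alone, with a mean log2 fold change of 0.87. NDRG1, a hypoxia-inducible stress gene, rose from 62.6 ± 8.01 to 277 ± 28.6 FPKM (log2 fold change 2.13, SE 0.11, limma adjusted p = 3.46e-05). The glycolytic enzymes PGK1 and ALDOA rose from 425 ± 15.3 to 829 ± 54.9 FPKM and from 499.5 ± 26.7 to 811 ± 11.9 FPKM, and the endoplasmic reticulum oxidase ERO1A rose from 44 ± 5.26 to 109 ± 7.62 FPKM. This was the only list of 24 that camera called both with the preset correlation (adjusted p = 7.30e-20) and with an estimated correlation (adjusted p = 0.0243).

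Of 23 cholesterol synthesis genes, 5 fell, none rose and 18 did not pass the test (7 fell and 1 rose when adjusted over the list alone). Among them, INSIG1, which restrains sterol synthesis, went from 73.7 ± 8.55 to 38.4 ± 2.05 FPKM, FDPS from 122 ± 20 to 68.2 ± 3.78 FPKM and CYP51A1 from 84 ± 2.3 to 53 ± 5.89 FPKM. IDI1 went from 37.7 ± 4.77 to 18 ± 5.09 FPKM and was named after its values were seen. The list was called lower (camera adjusted p = 9.26e-05; adjusted p = 0.117 with an estimated correlation). CYP51A1 lost its call without NC replicate 3 (adjusted p = 0.0537). Of 17 fatty acid synthesis genes, 3 fell and 14 did not pass the test (7 fell and 1 rose when adjusted over the list alone): the NADPH-producing malic enzyme ME1, from 84.6 ± 5.92 to 31.8 ± 8.47 FPKM, the desaturase FADS2, from 346 ± 36.3 to 200.3 ± 12.6 FPKM, and fatty acid synthase FASN, from 148 ± 24.6 to 93.7 ± 10.4 FPKM. Camera called the list lower (adjusted p = 0.0197; adjusted p = 0.234 with an estimated correlation). FASN lost its call without NC replicate 2, NC replicate 3, oeALKBH5 replicate 1, oeALKBH5 replicate 2 and oeALKBH5 replicate 3 (adjusted p up to 0.0995, without NC replicate 3). Of 13 mitochondrially encoded genes, 4 fell, 1 rose and 8 did not pass the test (6 fell and 1 rose when adjusted over the list alone). MT-CO3 went from 6578 ± 209 to 5174 ± 316 FPKM and MT-CO2 from 1614 ± 90.3 to 1240.4 ± 73 FPKM, whereas MT-CO1 rose from 1988 ± 103 to 3948 ± 797 FPKM; the other members that fell were MT-ND1 and, named after its values were seen, MT-CYB. MT-CO3 had the highest value of each library, so quantile normalization sets it equal in all libraries and it has no fall on that scale (limma adjusted p = 1); without the trend its adjusted p was 0.176. The list was called lower (camera adjusted p = 0.0056; adjusted p = 0.168 with an estimated correlation; adjusted p = 0.089 with fry). Its mean log2 fold change of -0.20 turned to 0.20 without NC replicate 1. MT-ND3 was 1138 FPKM in NC replicate 1 and at most 0.738 FPKM elsewhere, and MT-ATP8 was a failed estimate in NC replicate 2. MT-CO2 lost its call without NC replicate 3 (adjusted p = 0.0604). MT-ND1 lost its call without NC replicate 2, NC replicate 3, oeALKBH5 replicate 2 and oeALKBH5 replicate 3 (adjusted p up to 0.0901, without NC replicate 3). Of 34 nuclear genes of oxidative phosphorylation, 2 fell, NDUFA2 from 47 ± 3.23 to 29 ± 3.86 FPKM and ATP5F1A from 478 ± 13.4 to 394 ± 19.5 FPKM, and 32 did not pass the test (also 2 falling when adjusted over the list alone). Camera called this list lower (adjusted p = 0.00301; adjusted p = 0.311 with an estimated correlation), but not under quantile normalization (adjusted p = 0.136), nor did the rotation test fry (adjusted p = 0.116). NDUFA2 lost its call without NC replicate 1, NC replicate 2, NC replicate 3 and oeALKBH5 replicate 3 (adjusted p up to 0.109, without NC replicate 3). ATP5F1A lost its call in each of the 6 fits that left out 1 library (adjusted p up to 0.133, without NC replicate 3).

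All 37 tested DNA replication genes had negative log2 fold changes, with a mean of -0.61; 15 fell and 22 did not pass the test (28 fell when adjusted over the list alone). The sliding clamp PCNA fell from 213 ± 14.3 to 96 ± 5.86 FPKM (log2 fold change -1.14, SE 0.09, limma adjusted p = 2.56e-04). Thymidylate synthase TYMS went from 114 ± 11.3 to 55.6 ± 3.94 FPKM, the helicase subunit MCM3 from 69.7 ± 3.18 to 38 ± 1.31 FPKM and the ribonucleotide reductase subunit RRM2 from 189.7 ± 10.9 to 119 ± 3.43 FPKM. Of 13 replication-dependent histone genes, 12 fell and 1 did not pass the test (also 12 when adjusted over the list alone), among them H3C4, from 265 ± 25.9 to 105 ± 14.9 FPKM, H4C3, from 933 ± 111 to 469 ± 34.6 FPKM, H2BC5, from 818 ± 64.6 to 426 ± 22.5 FPKM, and H2BC12, from 391 ± 30.4 to 211 ± 17.4 FPKM. Histone genes of one class are close copies, so the split of reads among them is uncertain. Camera called both lists lower (adjusted p = 2.48e-19 and 9.12e-16; adjusted p = 0.117 for each with an estimated correlation). Of 30 genes of the replication checkpoint and fork protection, 4 fell, CLSPN, FANCD2, from 35.7 ± 5.54 to 18.8 ± 1.8 FPKM, BRCA1, from 37.4 ± 4.12 to 20.3 ± 3.63 FPKM, and NBN, from 30.3 ± 4.26 to 17.7 ± 2.93 FPKM, and 26 did not pass the test (10 fell and 1 rose when adjusted over the list alone). Camera called this list lower (adjusted p = 2.62e-04; adjusted p = 0.168 with an estimated correlation). NBN lost its call in each of the 6 fits that left out 1 library, with adjusted p up to 0.135 without NC replicate 1. FANCD2 lost its call without NC replicate 1, NC replicate 3, oeALKBH5 replicate 1 and oeALKBH5 replicate 3 (adjusted p up to 0.0762, without NC replicate 3). BRCA1 lost its call without NC replicate 2, NC replicate 3 and oeALKBH5 replicate 3 (adjusted p up to 0.104, without NC replicate 3).

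Of 32 tested members of the mitosis list, 1 fell, the kinetochore motor CENPE, from 18.6 ± 2.58 to 8.03 ± 1.28 FPKM, and 31 did not pass the test (also 1 when adjusted over the list alone), with a mean log2 fold change of -0.20. That mean ran from -0.34 to -0.11 over the alternatives. Camera called the list lower (adjusted p = 0.00892), but not with an estimated correlation (adjusted p = 0.731) or with fry (adjusted p = 0.424), nor without NC replicate 2 (adjusted p = 0.189), NC replicate 3 (adjusted p = 0.0661), oeALKBH5 replicate 2 (adjusted p = 0.0523) or oeALKBH5 replicate 3 (adjusted p = 0.0756). CENPE lost its call without NC replicate 2 (adjusted p = 0.0561) and without NC replicate 3 (adjusted p = 0.0662). Of 29 MYC target and ribosome biogenesis genes, 5 fell and 24 did not pass the test (9 fell and 1 rose when adjusted over the list alone): the mitochondrial chaperonins HSPE1, from 289.6 ± 19.4 to 185 ± 4.44 FPKM, and HSPD1, from 858 ± 53.9 to 659.6 ± 16.9 FPKM, the snoRNP protein NOP56, from 146 ± 5.93 to 97.1 ± 12.7 FPKM, the pyrimidine synthesis enzyme CAD, from 27.6 ± 2.43 to 16.6 ± 1.14 FPKM, and SRM, from 77.4 ± 11.4 to 50 ± 6.08 FPKM, named after its values were seen. Camera called the list lower (adjusted p = 0.00151; adjusted p = 0.168 with an estimated correlation). HSPD1 lost its call without NC replicate 3 (adjusted p = 0.0517). NOP56 lost its call without NC replicate 1, NC replicate 2 and NC replicate 3 (adjusted p up to 0.0901, without NC replicate 3). CAD lost its call in each of the 6 fits that left out 1 library (adjusted p up to 0.113, without NC replicate 3).

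**Figure D3:**
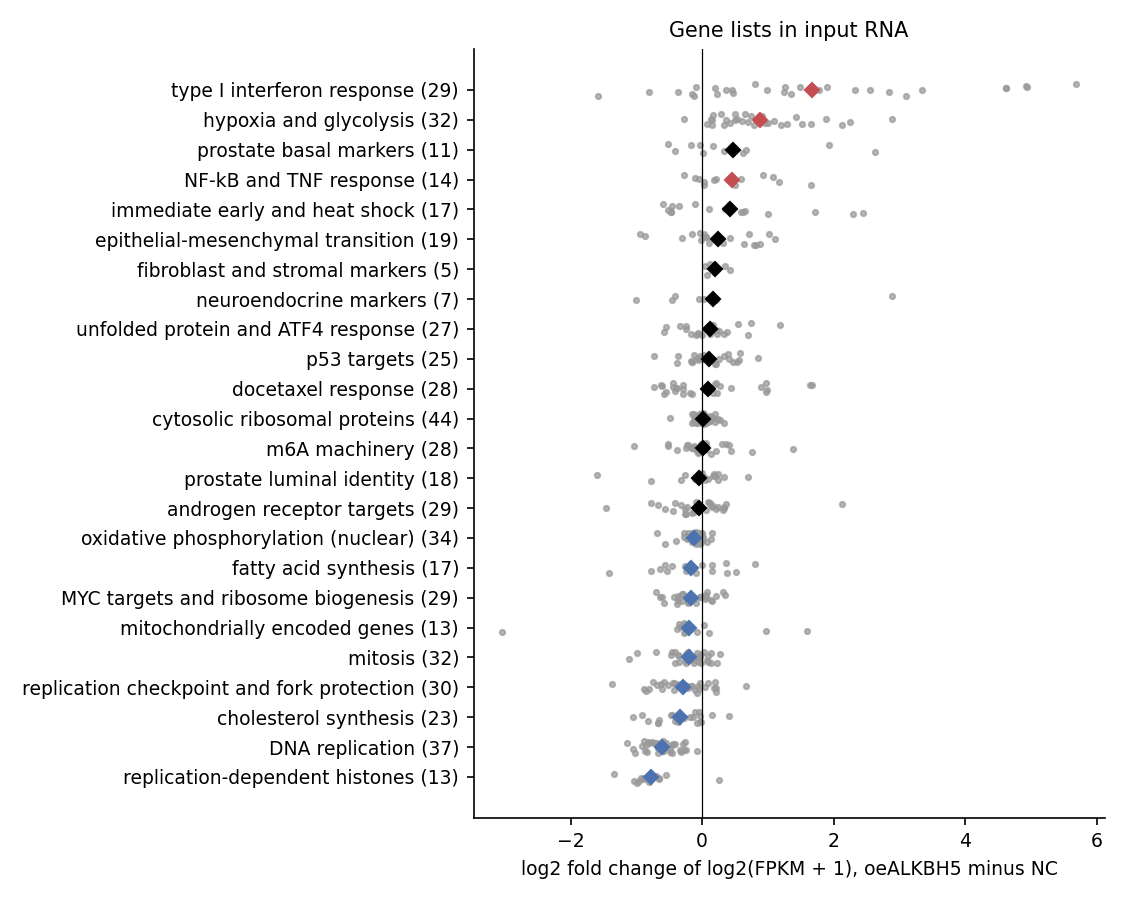
Log2 fold changes (oeALKBH5 minus NC, log2(FPKM + 1) scale) of the members of each gene list in input RNA, with the number of tested members in parentheses; grey points are genes, and diamonds are list means, red or blue where camera with the preset correlation called the list higher or lower and black where it did not. The means ran from -0.78 for the histones to 1.67 for the interferon list.

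Lists of prostate identity and drug response were not called as sets. KLK3, which encodes prostate-specific antigen and was named after its values were seen, stood at 1004 ± 14.8 FPKM in NC and 943 ± 52.8 FPKM in oeALKBH5 libraries (limma adjusted p = 0.356). Of 29 androgen receptor targets, 1 rose, NDRG1, 2 fell, SLC45A3 from 31.1 ± 3.41 to 17.9 ± 3.23 FPKM and C1orf116 from 60 ± 4.79 to 40.3 ± 4.72 FPKM, and 26 did not pass the test (4 rose and 6 fell when adjusted over the list alone). The list was not called by camera (adjusted p = 0.416). Both falls lost their calls in each of the 6 fits that left out 1 library (adjusted p up to 0.133 for SLC45A3 without NC replicate 3 and up to 0.116 for C1orf116 without NC replicate 1). Of 18 luminal identity genes, 1 rose, the keratin KRT8 from 137 ± 8.44 to 223 ± 13.2 FPKM, and 1 fell, SLC45A3 (3 rose and 2 fell when adjusted over the list alone). As a set it was not called (camera adjusted p = 0.649). Of 11 basal markers, 3 rose, TRIM29, from 0.251 ± 0.434 to 7.04 ± 4.07 FPKM, LAMA3, from 59.7 ± 11 to 94.4 ± 7.23 FPKM, and KRT15, from 0.185 ± 0.208 to 3.92 ± 2.6 FPKM (also 3 when adjusted over the list alone). Camera did not call this list (adjusted p = 0.0771). Of 7 neuroendocrine markers, 1 rose, ENO2, also a glycolytic enzyme, from 5.18 ± 4.58 to 37.5 ± 2.52 FPKM (also 1 when adjusted over the list alone). The list was not called by camera (adjusted p = 0.938). LAMA3 lost its call without NC replicate 1, NC replicate 2, oeALKBH5 replicate 1, oeALKBH5 replicate 2 and oeALKBH5 replicate 3 (adjusted p up to 0.101, without oeALKBH5 replicate 3). KRT15 lost its call without NC replicate 1, NC replicate 2, NC replicate 3, oeALKBH5 replicate 1 and oeALKBH5 replicate 2 (adjusted p up to 0.133, without NC replicate 3).

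Docetaxel stabilises microtubules, and the list of docetaxel response genes moved in both directions. Of 28 tested members, 4 rose, 3 fell and 21 did not pass the test (6 rose and 7 fell when adjusted over the list alone). As a set it was not called (camera adjusted p = 0.692). The tubulin isotypes TUBB3 and TUBB4A rose from 3.37 ± 1.83 to 11.8 ± 0.443 FPKM and from 3.89 ± 1.28 to 14.4 ± 3.11 FPKM, and the apoptosis inhibitor XIAP rose from 27 ± 1.57 to 51.2 ± 8.09 FPKM, whereas the abundant isotype TUBA1B fell from 572 ± 59.6 to 382 ± 46 FPKM. The other called members, named after their values were seen, were the microtubule-binding protein MAPT, which rose, and the tubulins TUBA4A and TUBB4B, which fell. The drug efflux pump ABCB1 stood at 2.5 ± 0.703 FPKM in NC and 5.88 ± 1.69 FPKM in oeALKBH5 libraries (limma adjusted p = 0.0963), also named after its values were seen. TUBB3 lost its call without NC replicate 1 (adjusted p = 0.0591) and without oeALKBH5 replicates 1 (0.0652), 2 (0.0644) and 3 (0.0754). TUBA1B lost it without NC replicates 2 (0.0599) and 3 (0.0799) and without oeALKBH5 replicates 2 (0.0544) and 3 (0.0601), and XIAP without NC replicate 3 (0.0515).

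In the remaining lists few genes passed the test. Of 25 p53 targets 1 rose, CDKN1A, from 40.1 ± 4.73 to 59.4 ± 2.85 FPKM (also 1 when adjusted over the list alone). Camera did not call this list (adjusted p = 0.449). Of 27 unfolded protein and ATF4 response genes 3 rose (also 3 when adjusted over the list alone; camera adjusted p = 0.249): DDIT3, from 25.1 ± 5.53 to 58.1 ± 10.2 FPKM, DDIT4, from 84.5 ± 7.48 to 142 ± 8.9 FPKM, and STC2, from 30.9 ± 5.5 to 50.4 ± 3.21 FPKM. Of 19 epithelial-mesenchymal transition genes 1 rose, fibronectin FN1, from 98.4 ± 7.55 to 182 ± 1.9 FPKM (3 when adjusted over the list alone). The list was not called by camera (adjusted p = 0.0533). Of 44 cytosolic ribosomal protein genes 2 rose, RPL10 and RPL7, and 1 fell, RPS28 (also 2 and 1 when adjusted over the list alone). As a set it was not called (camera adjusted p = 0.692). None of 5 fibroblast and stromal markers was called by limma, over all genes or over the list alone (camera adjusted p = 0.692). Without oeALKBH5 replicate 1, camera called the basal (adjusted p = 0.0347), unfolded protein (adjusted p = 0.029) and epithelial-mesenchymal (adjusted p = 0.0314) lists higher, and it called the last of these also without NC replicate 1 (adjusted p = 0.0241) and NC replicate 3 (adjusted p = 0.0308). CDKN1A lost its call without NC replicate 2, NC replicate 3, oeALKBH5 replicate 1, oeALKBH5 replicate 2 and oeALKBH5 replicate 3 (adjusted p up to 0.118, without NC replicate 3). STC2 lost its call without NC replicate 1, NC replicate 2, oeALKBH5 replicate 1, oeALKBH5 replicate 2 and oeALKBH5 replicate 3 (adjusted p up to 0.0925, without oeALKBH5 replicate 3). RPL10 lost its call without NC replicate 3 (adjusted p = 0.0577) and without oeALKBH5 replicate 3 (adjusted p = 0.0509). RPL7 lost its call without NC replicate 1, NC replicate 3, oeALKBH5 replicate 1, oeALKBH5 replicate 2 and oeALKBH5 replicate 3 (adjusted p up to 0.133, without NC replicate 3).

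Genes of the m6A machinery moved singly. Of 28 tested members, 2 rose, 2 fell and 24 did not pass the test (3 rose and 2 fell when adjusted over the list alone). Camera did not call this list (adjusted p = 0.692). The m6A-associated reader HNRNPA2B1 fell from 709 ± 22.4 to 347 ± 45.3 FPKM (log2 fold change -1.04, SE 0.09, limma adjusted p = 5.60e-04) and PRRC2A from 96 ± 5.99 to 73.6 ± 2.5 FPKM, while YTHDF3, a cytoplasmic reader, rose from 36.6 ± 4.71 to 62.5 ± 9.53 FPKM beside IGF2BP2. PRRC2A lost its call in each of the 6 fits that left out 1 library (adjusted p up to 0.167 without NC replicate 3), and YTHDF3 without NC replicates 1 (0.0773) and 3 (0.0901) and oeALKBH5 replicates 2 (0.0801) and 3 (0.0865). The methyltransferase METTL3 stood at 21.6 ± 2.48 FPKM in NC and 14.9 ± 3.13 FPKM in oeALKBH5 libraries (limma adjusted p = 0.153), and the other m6A demethylase, FTO, at 34 ± 4.98 and 43.9 ± 7.25 FPKM (limma adjusted p = 0.232). In the m6A machinery, luminal, neuroendocrine and docetaxel lists the mean, the median and the direction of camera differed in sign.

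The third comparison asked how m6A differed between NC cells and cells labelled as overexpressing its demethylase, from the peak list of each IP library. Whether a peak is called also depends on the expression of its transcript. A peak or region in the lists of 1 group only need not be a difference in m6A. The lists also seem to have been processed after calling by steps not stated, so counts and widths describe them as deposited. The NC lists held 11902, 11559 and 11619 peaks in replicates 1, 2 and 3, and the oeALKBH5 lists held 16060, 11478 and 15052. The means were 11693 ± 183 and 14197 ± 2408 peaks (SD, n = 3). An exact permutation test of the difference gave p = 0.4, where the smallest possible is 0.1, and oeALKBH5 replicate 2 had fewer peaks than each NC library. oeALKBH5 replicates 1 and 3 carried the excess: their peaks were shorter, with medians of 287 and 272 bases against 354 to 379 in NC and 369 in oeALKBH5 replicate 2. The covered length was 8.14 ± 0.204 megabases in NC and 8.45 ± 0.765 megabases in oeALKBH5 (exact permutation p = 0.7). The share of peaks with an authors' score under 100 was 26.8 ± 0.361% in NC lists and 32 ± 3.31% in oeALKBH5 lists (exact permutation p = 0.1).

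Peaks of the 6 libraries joined into 25666 regions, of which 5809 (22.6%) held a peak in all 6 libraries and 10015 (39.0%) in 1. A total of 123 regions were present in all NC and no oeALKBH5 libraries (lost), and 251 in all oeALKBH5 and no NC libraries (gained). By presence or absence of a peak, no single region can pass an exact test at 3 libraries against 3, whose smallest p is 0.1. With the same number of peaks from each list, the 11478 with the highest scores, the direction turned: 190 regions were lost and 130 gained. This cut removes low-scoring peaks mostly from oeALKBH5 replicates 1 and 3, so it works against gained regions. Without oeALKBH5 replicate 2, the shortest list, 227 were lost and 935 gained. Leaving out any library asks for fewer lists, which raises both counts. Without oeALKBH5 replicate 1, 330 were lost and 509 gained, and without oeALKBH5 replicate 3, 219 were lost and 541 gained. The lost regions had a median within-list score percentile of 26.0 and the gained regions of 34.4, so most were weak peaks.

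The highest-ranked lost regions (hg19, 1-based) were on chromosome 1 at 70716291 to 70717701 (plus strand), chromosome 16 at 28548662 to 28548990 (minus) and chromosome 19 at 45911391 to 45914024 (plus), each at a mean score percentile of 96.7, followed by chromosome 2 at 238820170 to 238820759 (plus) at 83.6 and chromosome 19 at 8531119 to 8531272 (plus) at 78.1. The other 5 of the 10 ranked from 59.3 to 69.9. The highest-ranked gained regions were on chromosome 1 at 93307323 to 93307481 (plus) at 97.4, chromosome 19 at 45910591 to 45912983 (minus) at 96.7, chromosome 17 at 40139837 to 40139928 (minus) at 93.4, chromosome 16 at 72135399 to 72135511 (plus) at 93.1 and chromosome 20 at 25843696 to 25843837 (minus) at 89.5. The other 5 of the 10 ranked from 81.2 to 88.9. The lost and the gained region on chromosome 19 near 45.9 megabases cover shared bases on opposite strands, with different ends. Whether this pair is a change in the strand the lists give or separate peaks of each strand was not tested. Neither is therefore a clear loss or gain, although both stand in the counts above. Genes were not assigned to these regions, because an annotation of hg19 was not used here.

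**Figure D4:**
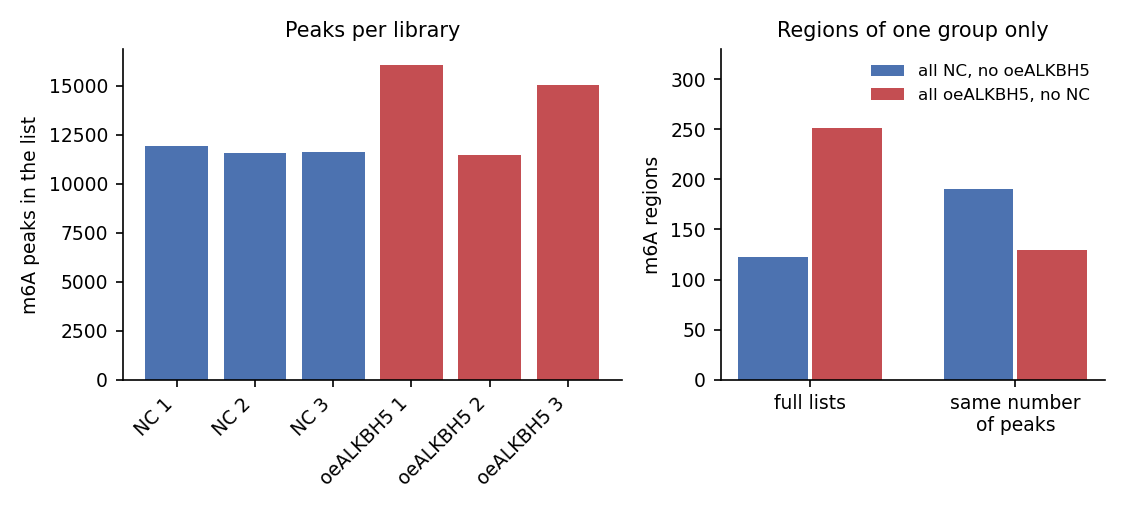
Left, number of m6A peaks in the list of each IP library (NC blue, oeALKBH5 red); right, number of m6A regions present in all libraries of one group and none of the other, from the full lists and from the 11478 highest-scoring peaks of each list. The full lists gave 123 lost and 251 gained regions, and the lists of equal length 190 and 130.

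NC libraries shared more peaks with each other than with oeALKBH5 libraries, and oeALKBH5 libraries did not. The Jaccard index of covered bases averaged 0.636 among NC libraries, 0.563 among oeALKBH5 libraries and 0.579 between the groups. All 6 lists held 3328 identical intervals, which count as shared in each of these values. The mean within groups exceeded that between groups by 0.0207 (exact p = 0.1 over the 10 splits, the smallest possible), and by 0.0173 in the share of peaks that overlap (exact p = 0.1).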

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

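Of 136 named genes, 86 kept their side of the threshold in every alternative they were tested in, and 0 called genes changed direction. These 86 include genes that were never called. Of 83 named genes that were called, 46 kept their call in every fit that left out 1 library. The other 37 lost it in at least 1 such fit. Of the 136, 126 were tested in all 14 alternatives and the rest in at least 12, as a filter left them out. Of 24 gene lists, 8 kept their side of the threshold, 23 of the 24 being tested in all 12 alternatives and the fibroblast and stromal list in 10. Among the 12 lists called, hypoxia and glycolysis was the only one that stayed called in every alternative. The rest of the 8 were lists that were never called. Lists not called in the report were called higher in some alternatives: the immediate early and heat shock list with fry (adjusted p = 0.00131), the epithelial-mesenchymal list with fry (adjusted p = 0.0328), with a pseudocount of 0.1 (adjusted p = 0.0386) and without genes with failed estimates (adjusted p = 0.0489), the basal list without those genes (adjusted p = 0.0439), and the unfolded protein and ribosomal protein lists under quantile normalization (adjusted p = 0.0395 and 0.0242). The cause was not tested. The number of changed genes was 421 without a filter (163 lower), where more genes were tested, and 270 without the limma trend (198 higher, 72 lower), whose cause was not tested. Leaving out 1 library, which leaves fewer samples, gave 232 to 436 changed genes, 156 to 226 higher and 76 to 210 lower, 10 to 15 called lists, and a log2 fold change of ALKBH5 of 0.25 to 0.34. Camera called 1 list with an estimated correlation. Equal numbers of peaks gave 190 lost and 130 gained regions. Regions in at least 2 of 3 libraries, a looser rule by construction, numbered 2075, of which 589 were lost and 1486 gained. Leaving out 1 library, which asks for fewer lists, gave 665 to 1162 such regions, 219 to 330 lost and 387 to 935 gained, and a difference in peaks per library of 1571.7 to 3862.7. Alternatives chosen after the data were seen, without regard to strand, without peaks under 50 bases and without genes with failed estimates, changed none of these counts by over 1.5 times. The overlap of 50% of the shorter peak leaves the Jaccard index of bases unchanged by construction. Alternatives on the expression of genes with lost or gained regions were not run. With FPKM alone, low genes are limited by an unknown depth.

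With the replicate number as a block, limma called 344 genes, 203 higher and 141 lower, and the same lists; the cause was not tested. Residuals of libraries with the same number correlated at -0.017, -0.021 and 0.032, and those of other pairs at -0.033 to 0.046. No variation shared by number was therefore seen. With 3 libraries per group, this cannot show whether the libraries were paired.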

Other observations

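Interferon genes themselves were among the antiviral genes measured, and the genes in this paragraph and the next were chosen after the results were seen, as tests, not predictions. IFNL1, a type III interferon, was listed at 0 in all 3 NC libraries and at 4.94, 2.7 and 2.54 FPKM in the oeALKBH5 libraries, and rose by the limma test (adjusted p = 0.00977). IFNB1, the type I interferon of most cells, was listed at 0 in all NC libraries and at 0.507, 3.47 and 1.96 FPKM in the oeALKBH5 libraries (limma adjusted p = 0.0945). The transcription factor IRF1 rose from 1.87 ± 1.34 to 7.17 ± 0.778 FPKM (limma adjusted p = 0.0331).

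Genes of MHC class I antigen presentation, which display peptides to T cells, moved in part: of 16 tested members 4 rose, HLA-B, HLA-C, HLA-E and B2M, and none fell (camera adjusted p = 0.00498; adjusted p = 0.184 with an estimated correlation). Of 16 genes of the cytosolic chaperonin and HSP90, which fold new proteins, 10 fell and none rose, with a mean log2 fold change of -0.38 (camera adjusted p = 1.10e-11; adjusted p = 0.122 with an estimated correlation). Of 32 translation factors 8 rose and 2 fell (camera adjusted p = 0.767). These 3 lists were chosen after the results were seen, on the same libraries.

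The 3 patterns below were chosen after the results were seen, and their explanations are hypotheses, so these are tests, not predictions. What each outcome would mean was written before the test for JAK1, for scaling and for equal peak lists, and after the values were known for the others. The first pattern is the rise of interferon genes. For leukocytes or blood in the oeALKBH5 cultures, the 13 immune markers rose in sum by 0.734% of the rise of the tested interferon genes, 5.03 against 685 FPKM. The marker rise was small beside that of the interferon genes. How it scales with the number of such cells was not measured, so the ratio does not exclude them. A reaction to the introduced construct or its delivery cannot be told apart from an effect of ALKBH5. The interferon list's mean log2 fold change of 1.67 (SE 0.36 over genes) came with 1 construct only. Interferon genes rose while STAT2 and IRF7 were not called and IRF9 had an uncertain fall, and a lack of JAK1 mRNA could be one reason; JAK1 ranged from 1.55 to 7.32 FPKM, neither under 1 nor above 5 in every library as the test asked, which leaves the hypothesis open.

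The second pattern is the fall of DNA replication and histone genes. Fewer cycling cells of all phases would lower both lists alike. The mean of the mitosis list lay 0.42 (SE 0.07 over genes) above that of the DNA replication list on the log2 scale. An SE over genes does not measure the spread between libraries. With other groupings of the same libraries the size of the mitosis mean reached 0.384, beyond its -0.199 under the labels. The comparison therefore cannot settle this explanation. Scaling between libraries would bring the fall near 0 under quantile normalization, but the mean of the DNA replication list was then -0.61 (SE 0.04 over genes). Denser or less oxygenated oeALKBH5 cultures at harvest cannot be told apart from an effect of ALKBH5. The hypoxia and glycolysis list had a mean of 0.87 (SE 0.13 over genes) in the same libraries, and the labels give no density.

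The third pattern is that more m6A regions were gained than lost in the oeALKBH5 libraries. Longer peak lists in 2 oeALKBH5 libraries were tested as the cause: with 11478 peaks per library, the ratio of gained to lost regions was 0.68. The excess of gained regions thus went with list length. The cut by score takes weak peaks mostly from the long lists, however, and a true gain of weak peaks would also lengthen a list. The test therefore cannot tell list length from such a gain. Deeper sequencing of IP libraries may lie behind the longer lists; the mean highest peak number of all 3 oeALKBH5 lists was 1.09 times that of the NC lists. It was 169660 and 175819 in the long lists of replicates 1 and 3, 150232 in replicate 2 and 150667 to 152364 in NC, so it was highest in the 2 long lists. The depth is unknown, so deeper sequencing cannot be told apart from other causes of longer lists.

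Regrouping the libraries gives 10 splits, too few for a share under 0.05. In 1 of 10 splits, the labelled one, as many genes were called: 695, against at most 3 in another split. For lists it was also 1 of 10, 12 against at most 10, and for regions in one direction 1 of 10, 251 gained against at most 205. From the full lists the 123 lost regions do not stand out, since several other splits gave 124 to 205 in one direction. With 11478 peaks per library, the labelled split gave 190 lost and 130 gained regions, against at most 121 in one direction of another split, so the larger count was then that of the lost regions.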
